A study of Mus musculus with 6 samples.

How the data were processed

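Per the labels, the 6 arrays were hybridised with RNA from testis of C57BL/6 mice. MVH, also called DDX4, is a DEAD-box RNA helicase of germ cells. RNA immunoprecipitation pulls a protein out of a lysate with an antibody and recovers the RNA that comes with it. Per the labels' protocols, cells were dispersed from testes and lysed, the cleared lysate was incubated overnight with an antibody against MVH or with normal rabbit IgG, and bound RNA was extracted after the beads had been washed. The third group is total RNA taken with no antibody, labelled WCE, and is called total RNA here. Each group holds 2 arrays, numbered 1 and 2 in the labels. Part of the labels' protocol text describes another kind of sample and was not used. The labels do not say whether the numbered arrays came from separate animals, so p-values measure the spread between these samples, which may be technical.

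Per the labels' protocols, RNA was amplified to aminoallyl aRNA and coupled to Cy5, with 1 sample per array. The values are the intensity of each probe on a linear scale, as the authors deposited it. The scanner, the background correction, the scaling method and the rule for blank cells are not given in the sources used here. The deposited intensity had a median of 30 on 5 of the arrays and of 20.8 on the array of IgG precipitate 2. Between 508 and 1383 of the 23473 probes were blank per array, with the most blanks on IgG precipitate 2. Those blank on an array but listed elsewhere were dim there, with a median intensity of 2.38 to 2.8 on the other arrays against 28.2 to 33.5 for listed probes. The lowest values listed lay between 1.3 and 2. The highest lay between 67580 and 83665, so that very bright probes may be compressed by saturation. The number of arrays limits the precision.

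Gene names came from the platform annotation: 16631 probes had 1 gene symbol, 0 had several and 6842 had none in the annotation used here. Symbols were updated through the synonyms of the RefSeq annotation of mouse assembly GRCm38.p6, which was used for names and for the length of each gene's genomic span only. Of the symbols, 12622 were already current, 3947 were updated and 62 were not matched, which gave 16390 different symbols. The deposited table names no genome build, so no coordinates are given.

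Intensities were converted to log2 and each array was centred on the median of its listed values. For display they were scaled back to an array median of 30. A linear model was fitted to all 6 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), so that the groups share 1 estimate of the spread. This left 3 residual degrees of freedom for a probe listed on every array, and the prior added 5.77. A contrast was tested at a probe only where all 4 arrays of its groups had a value. Adjusted p-values are Benjamini-Hochberg values over the probes tested in a contrast, with a threshold of 0.05. The median standard error of a log2 difference was 0.31. Plots were drawn with matplotlib 3.10.9.

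The comparisons were the MVH precipitate against the IgG precipitate, each precipitate against total RNA, and the probes higher in the MVH precipitate than in both controls. A count by size took probes at least 2-fold higher in the lower MVH array than in the higher IgG array, with no test. For 17 gene lists, written before the data were examined, camera compared each list with all other genes, with a preset correlation of 0.01, over 15130 genes with 1 probe each listed on all 6 arrays. Its p-values were adjusted over the 17 lists of a contrast, which gave 51 tests. The probe of a gene was the one with the highest mean. Another 6 lists were drawn up after the data had been seen. The text names the 10 genes with the largest rise and the 10 with the largest fall in each contrast, among those past the threshold whose groups did not overlap. It also names up to 4 members of a list by size of change, and the genes fixed by name (Ddx4, Eif4b, Hat1, Snd1, Actb, Gapdh, Prm1 and Tnp1). Identifiers without a descriptive symbol were passed over. Genes named outside this rule are said to be so.

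The same steps were tested on simulated data for the comparison of the 2 precipitates, with 21241 probes. They recovered 5.97% of the probes changed 2-fold, 79.1% of those changed 4-fold and 100% of those changed 8-fold, with 3 false calls. A list of 40 genes shifted by 0.5 on the log2 scale was recovered. Each probe was simulated independently, whereas the estimated correlation within a list reached 0.483 in the data. Recovery of the list therefore does not speak for lists of correlated genes. Only 67, 67 and 66 probes were changed at the 3 sizes, against 1719 called in the data, so the percentages need not carry over.

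The alternatives tried were the values as deposited with no centring, quantile normalization, centring on the 75th percentile, leaving out the dimmest 25% of probes, an offset of 3.9 before log2, 1 probe per gene symbol, probes listed on all 6 arrays, a variance trend with robust eBayes, only the groups compared, the replicate number as a block, each array left out in turn, and camera with an estimated correlation. Camera with an estimated correlation also tests on the 3 residual degrees of freedom, which leaves it little power. A call lost with it need not be due to correlation between the genes. A median over probes listed on all 6 arrays and a threshold of 0.10 were added after the data had been seen.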

Results

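Total RNA of mouse testis, RNA brought down by an antibody against the germ cell helicase MVH, and RNA brought down by normal rabbit IgG were each measured on 2 arrays. Each array listed 22090 to 22965 of 23473 probes. Across 21241 probes listed on all 6 arrays, the log2 values of the 2 arrays of a group correlated at 0.986 for the MVH precipitate, 0.978 for the IgG precipitate and 0.988 for total RNA. The SD of their log2 difference was 0.47, 0.60 and 0.45. The arrays of the MVH precipitate correlated at 0.978 to 0.985 with those of total RNA and at 0.958 to 0.963 with those of the IgG precipitate. Those of the IgG precipitate correlated at 0.969 to 0.972 with those of total RNA.

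The first comparison asked which RNAs stood higher, relative to the array median, in the MVH than in the IgG precipitate. Because RNA was amplified and each array was centred, the amount of RNA recovered was not measured. A probe lower with MVH need not be less abundant there. Adam5, of the ADAM family of membrane proteins, was 12.6-fold higher with MVH (log2 3.65 ± 0.42, SE, n = 2 per group, limma adjusted p = 0.0148), with scaled intensities of 507 and 1230 in the MVH precipitates against 73.7 and 53.5 with IgG. Atp1a4, the sodium pump subunit of sperm, was higher by 3.89 ± 0.46, but was dim with IgG, at 7.2 and 2.88 against 60.4 and 75.3, so that its size and rank are uncertain (2.91 with an offset before log2). Kif2b, a microtubule-depolymerising kinesin, was higher by 3.45, the sulfide oxidising enzyme gene Sqor by 3.43, Rnft1 by 3.40 and Srp54a, of the signal recognition particle, by 3.29. Hk1, a hexokinase, was higher by 2.99, Mlf1 by 2.93, the mRNA-binding Y-box protein gene Ybx1 by 2.91 and the spindle protein gene Aspm by 2.84. Aspm was dim, at 21.5 and 19.2 against 2.8 and 2.88, and so was Rnft1 with IgG, at 8.5 and 4.33, so that the size and rank of both are uncertain (1.72 and 2.66 with an offset).

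The largest differences in the other direction were led by Gsn, which encodes the actin-severing protein gelsolin. It was lower in the MVH precipitate by 10.1-fold (log2 -3.33 ± 0.32, SE, n = 2 per group, limma adjusted p = 0.0112), at 723 and 461 against 4880 and 6900 with IgG. Sfxn3, a mitochondrial carrier gene, differed by -3.18, Fam160b2 by -3.12, Spag7 by -2.93 and the ubiquitin ligase gene Trim25 by -2.89. Cyp17a1, an enzyme of androgen synthesis in Leydig cells, differed by -2.59, and the estrogen sulfotransferase gene Sult1e1 by -2.51. Pf4 differed by -2.53, a size and rank that are uncertain because it was dim with MVH at 2.6 and 3.4 (-1.63 with an offset), Ebpl by -2.51 and Cmc2 by -2.50.

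**Figure D1:**
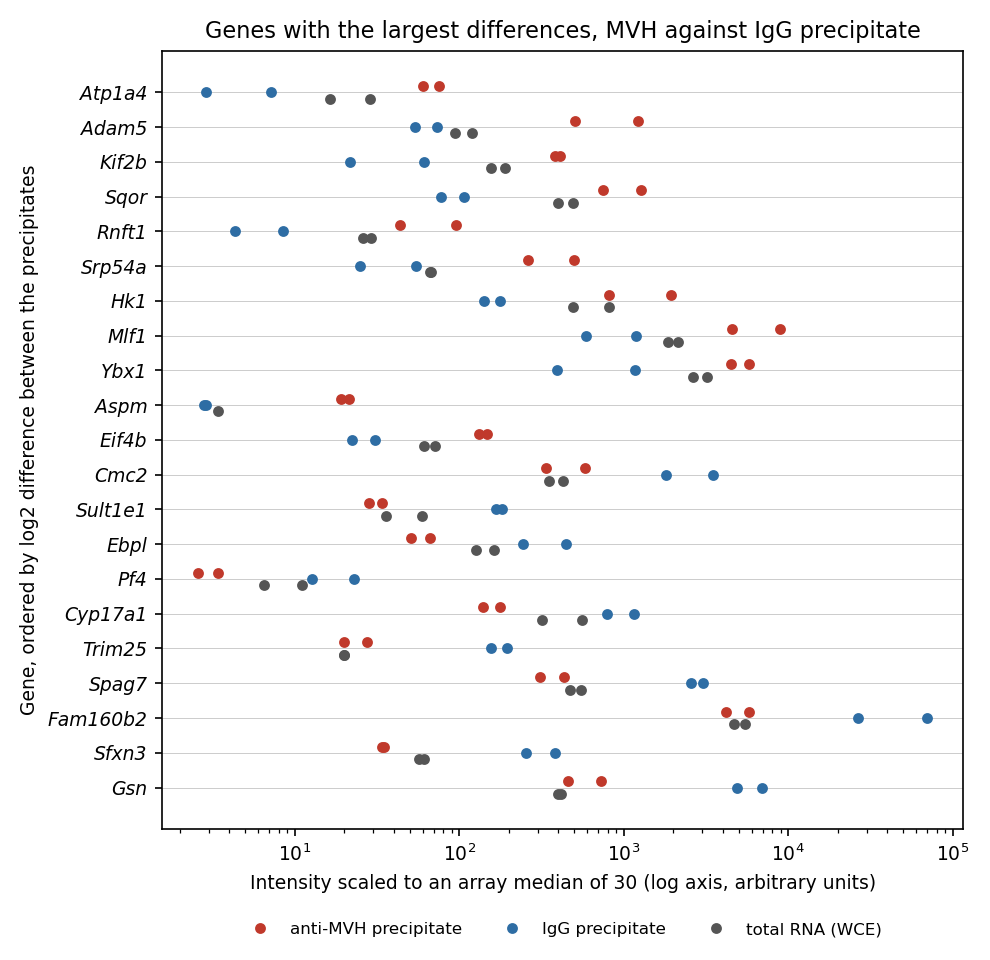
Scaled intensity (array median 30, log axis) on each of the 6 arrays for the 10 genes with the largest rise, the 10 with the largest fall and Eif4b, 1 point per array with a listed value (Aspm was blank on total RNA 2). For Adam5 both MVH precipitates (507 and 1230) lie above total RNA (120 and 94.5), whereas for Gsn both IgG precipitates (4880 and 6900) lie above total RNA (414 and 396).

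Of the genes fixed by name, Eif4b, a translation initiation factor, was 5.36-fold higher in the MVH than in the IgG precipitate (log2 2.42 ± 0.29, SE, n = 2 per group, limma adjusted p = 0.0148). Its scaled intensities were 148 and 132 with MVH, 30.6 and 22.2 with IgG, and 71.1 and 61.0 in total RNA. The mRNA of MVH itself, Ddx4, differed by 0.05 ± 0.30 (adjusted p = 0.944). Hat1, a histone acetyltransferase gene, differed by 0.95 ± 0.38 (adjusted p = 0.159) and Snd1 by -0.10 ± 0.28 (adjusted p = 0.863). Actb differed by -0.40 and Gapdh, whose probe was dim, by 0.80, neither past the threshold. Prm1 and Tnp1, which package sperm chromatin, differed by -0.05 and -0.15. Both lay near the top of the scale, where saturation would hide a difference.

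Genes of spermatids stood higher in the MVH precipitate than other genes did. Of 47 round spermatid and acrosome genes, 9 were higher and 0 lower (17 and 1 when adjusted over the list alone), with a median log2 difference of 0.62 (camera adjusted p = 1.71e-05, adjusted p = 0.61 with an estimated correlation). The 9 included Adam5, Hk1, the sperm glycolytic gene Pgk2 (2.13) and the sperm calcium channel gene Catsper4 (2.12). Of 46 elongating spermatid genes, 8 were higher and 1 lower (11 and 1 when adjusted over the list alone), with a median of 0.53 (camera adjusted p = 3.9e-05, adjusted p = 0.61 with an estimated correlation). Spata20 (2.43), Akap3 (2.08), Klhl10 (1.82) and Spata18 (1.74) were the largest. A second, dimmer probe of Spata20 did not pass. Without MVH precipitate 2 the median of the elongating spermatid genes was 0.30, and with no centring it was 0.79. Leaving out the centring moved all genes alike, and the median of all probes went from 0.07 to 0.34.

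Leydig cell, ribosomal and respiratory chain genes stood lower. Of 15 Leydig cell markers, 0 were higher and 6 lower (0 and 7 when adjusted over the list alone), with a median of -1.01 (camera adjusted p = 1.71e-05, adjusted p = 0.61 with an estimated correlation). Besides Cyp17a1 these included the steroid enzyme genes Cyp11a1 (-2.17), Hsd3b6 (-1.98) and Hsd3b1 (-1.88). Without IgG precipitate 1 the Leydig median was -0.425. Of 57 ribosomal protein genes, 0 were higher and 6 lower (0 and 10 when adjusted over the list alone), with a median of -0.43 (camera adjusted p = 1.71e-05, adjusted p = 0.61 with an estimated correlation). Rpl39 (-1.51), Rps25 (-1.48), Rps27 (-1.47) and Rps14 (-1.20) were the largest. Of 77 nuclear genes of the respiratory chain, 0 were higher and 5 lower (the same counts when adjusted over the list alone), with a median of -0.47 (camera adjusted p = 2.02e-06, adjusted p = 0.61 with an estimated correlation). Ndufa4 differed by -1.90 and Cox8a by -1.36. The respiratory median was -0.27 without IgG precipitate 1, and with no centring the ribosomal and respiratory medians were -0.165 and -0.20, while the median of all probes became 0.34.

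Lists with smaller shifts were lower by camera too. For mRNA decay and small RNA silencing factors the median was -0.18 (adjusted p = 0.0332, adjusted p = 0.61 with an estimated correlation), with 4 higher and 3 lower of 53 (4 and 6 when adjusted over the list alone). Lsm3 (-1.95), Tnrc6c (-1.88) and Edc4 (-1.50) were lower and the decapping gene Dcp1a (1.37) higher. For spermatogonial markers the median was -0.26 (adjusted p = 0.0332, adjusted p = 0.61 with an estimated correlation), with 1 higher, Dmrtb1 (1.53), and 5 lower of 27 (1 and 7 when adjusted over the list alone), among them Ccnd2 (-1.70) and Tex101 (-1.70). For replication-dependent histone genes it was -0.40 (adjusted p = 0.0137, adjusted p = 0.61 with an estimated correlation), with 0 of 18 past the threshold either way. All 3 calls were lost without MVH precipitate 1 (adjusted p = 0.126, 0.061 and 0.061), those of mRNA decay factors and histone genes without IgG precipitate 1 (0.0601 and 0.0841), that of spermatogonial markers without IgG precipitate 2 (0.0932) or the dimmest 25% of probes (0.0604), and that of mRNA decay factors with an offset (0.0587). The median of mRNA decay factors was -0.38 without MVH precipitate 2 and -0.36 without IgG precipitate 2, that of spermatogonial markers -0.16 without IgG precipitate 2, and that of histone genes -0.135 without IgG precipitate 1. With no centring the medians of the first 2 became 0.09 and 0.00, and that of histone genes -0.14. Leaving out the centring moves all genes of a contrast alike, and the median of all probes went from 0.07 to 0.34. Relative to the other genes these lists stayed lower, and all 3 still passed (camera adjusted p = 0.0395, 0.0277 and 0.0257).

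The list of the piRNA pathway and germ granules, the structures in which MVH lies, was not shifted (median -0.09, camera adjusted p = 0.271), yet 3 of its members were higher and 5 lower of 30 (5 and 10 when adjusted over the list alone). The helicase gene Ddx25 (2.51), Kif17 (2.10) and Rnf17 (1.94) were higher and Gpat2 (-2.07) lower. Of 45 translation initiation factors, 4 were higher and 2 lower (5 and 6 when adjusted over the list alone; camera adjusted p = 0.915), with Eif4e2 at 1.53, Eif4a2 at -1.38 and Eif4a1 at -1.35. Of 40 meiotic prophase genes, 4 were higher and 2 lower (4 and 3 when adjusted over the list alone; camera adjusted p = 0.901), among them Sycp3 (1.79), Brca2 (1.61) and Tex15 (-1.29). Of 41 proteasome subunits, 2 were higher and 6 lower (3 and 9 when adjusted over the list alone; camera adjusted p = 0.0583), with Psmf1 at 2.16 and Psmb5 at -1.76. Of 49 division regulators, 3 were higher and 7 lower (5 and 7 when adjusted over the list alone; camera adjusted p = 0.091), with Ttk at 1.77 and Bub1b at -1.71. Peritubular and vascular markers had 0 higher and 5 lower of 23 (2 and 8 when adjusted over the list alone; camera adjusted p = 0.0583), led by the smooth muscle actin gene Acta2 (-2.42). Sertoli cell markers had 1 lower of 28, Defb36 (-1.80), also when adjusted over the list alone (camera adjusted p = 0.208). Macrophage, lymphoid and blood markers had 0 of 19 past the threshold either way (camera adjusted p = 0.971). Housekeeping genes had 0 higher and 2 lower of 21 (3 and 3 when adjusted over the list alone; camera adjusted p = 0.647). The lower ones were Hsp90ab1 (-1.43) and Tuba1b (-1.45), whose other probe was higher by 1.67. Proteasome subunits passed without MVH precipitate 2 (median -0.28, adjusted p = 0.0202) and without IgG precipitate 2 (-0.40, 0.00385), and so did division regulators (-0.39, 0.0481, and -0.35, 0.0274). Peritubular and vascular markers passed without MVH precipitate 2 (0.0276) or the dimmest 25% of probes (0.0274), with an offset (0.0421) and with no centring (0.0416, where their median turned to 0.03). With no centring the median of all probes likewise rose, from 0.07 to 0.34.

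**Figure D2:**
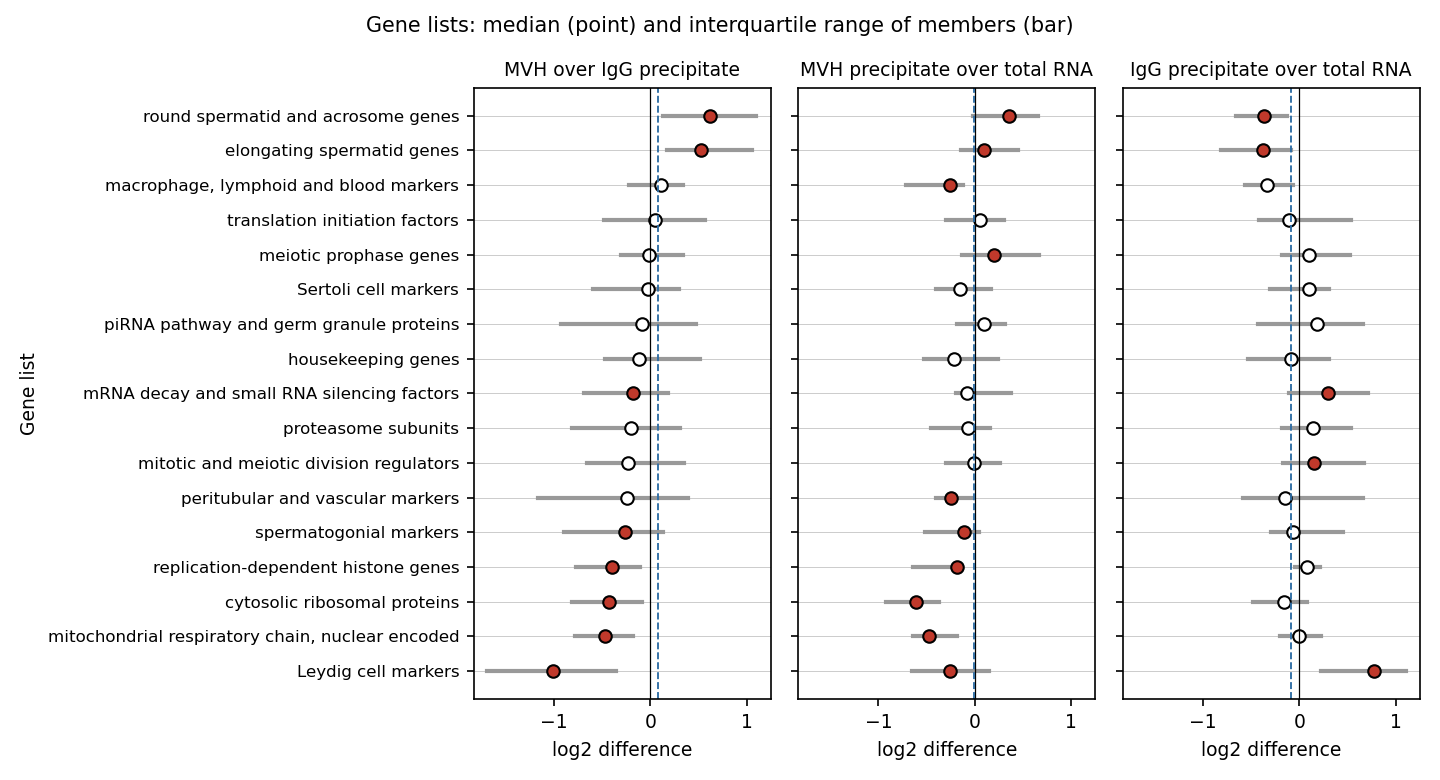
Median log2 difference (points) and interquartile range of the members (bars) of the 17 gene lists in each of the 3 comparisons, with filled points where camera passed an adjusted p of 0.05 and a dashed line at the median of all genes. Leydig cell markers lie at -1.01 between the precipitates and at 0.77 for the IgG precipitate over total RNA.

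In all, limma called 824 probes higher and 895 lower in the MVH than in the IgG precipitate, 7.97% of the 21574 tested. With the values as deposited, where IgG precipitate 2 has a lower median, the counts were 702 and 121. The called probes covered 644 named genes higher and 656 lower, and 417 called probes had no symbol. By size alone, 548 probes were at least 2-fold higher in both MVH than in both IgG arrays and 606 were 2-fold lower. These counts were 855 and 191 with no centring, 1371 and 905 without MVH precipitate 1, 784 and 1210 without MVH precipitate 2, 1357 and 1139 without IgG precipitate 1, and 1110 and 1655 without IgG precipitate 2. Another 89 probes were listed on both MVH arrays and blank on both IgG arrays, against 64 the other way round. The calls depended on the arrays that gave the spread, since 0 probes passed when only the 4 arrays compared were fitted. All calls were also lost when MVH precipitate 2 was left out, for a cause that was not tested, and when either total RNA array was. The total RNA arrays do not enter the difference between the precipitates, so their loss acts only through the shared estimate of the spread. The calls thus lean on the spread within total RNA. Its 2 arrays were the closest, with an SD of their log2 difference of 0.45, against 0.47 for the MVH and 0.60 for the IgG precipitate. Without MVH precipitate 1 the counts were 94 and 16.

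The second comparison set the MVH precipitate against total RNA, which shows enrichment relative to abundance. No named gene passed the threshold, and limma called 1 probe higher and 2 lower of 21793, none with a symbol (987 and 960 at an unadjusted p under 0.05, with 1090 expected by chance in both directions together). These low counts depend on the setting: 100 were higher and 23 lower without the dimmest 25% of probes, 72 and 20 with an offset, 132 and 48 with a variance trend, 23 and 7 with probes listed on all 6 arrays, 14 and 5 with no centring, and 0 and 0 with 1 probe per gene. These probes are named after their values were seen. Probe M400015034 had scaled intensities of 1210 and 1610 in the MVH precipitates against 32100 and 31560 in total RNA (log2 -4.51 ± 0.38, adjusted p = 0.0205), and was also lower than in the IgG precipitates (15630 and 32750). Probe M400000660 differed by -2.86 and probe M400000949 by 3.23. Among values that did not pass, Adam5 differed by 2.89 ± 0.42 (adjusted p = 0.122), Plcz1, the sperm factor that activates the egg, by 2.49 ± 0.39 (adjusted p = 0.122), and Eif4b by 1.09 ± 0.29 (adjusted p = 0.296). Ddx4 differed by 0.48 ± 0.30 (adjusted p = 0.736).

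Ribosomal protein genes were lower in the MVH precipitate than in total RNA as a group, with a median of -0.61 over 55 genes (camera adjusted p = 1.25e-18, adjusted p = 0.547 with an estimated correlation), 6 of them positive and 49 negative. None passed alone, and 16 were lower when adjusted over the list alone. Values included Rps27 at -1.55 and Rps14 at -1.50. Respiratory chain genes had a median of -0.47 over 77 genes (camera adjusted p = 3.3e-11, adjusted p = 0.549 with an estimated correlation), with Atp5e at -1.38. Round spermatid and acrosome genes had a median of 0.35 (camera adjusted p = 3.71e-05, adjusted p = 0.547 with an estimated correlation), and 2 of 47 were higher when adjusted over the list alone. Without MVH precipitate 2 the median was 0.16. Meiotic prophase genes had a median of 0.19 (camera adjusted p = 0.00393, adjusted p = 0.549 with an estimated correlation), with Meioc at 1.60 and Tex15 at 1.18, a call that was lost without total RNA 1 (median 0.10, adjusted p = 0.0567). Elongating spermatid genes had a median of 0.10 (camera adjusted p = 0.0432, adjusted p = 0.65 with an estimated correlation), with 2 of 46 higher when adjusted over the list alone and Crisp2 at 1.88. Their median turned to -0.08 without MVH precipitate 2 (adjusted p = 0.677), and the call was also lost without total RNA 1 (0.583) or the dimmest 25% of probes (0.0696). It was 0.22 without MVH precipitate 1 (adjusted p = 0.00287) or total RNA 2 (0.00307) and 0.28 with quantile normalization (0.00205).

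Some further lists had slightly lower values in the MVH precipitate than in total RNA. The medians were -0.19 for replication-dependent histone genes (camera adjusted p = 0.00393), -0.11 for spermatogonial markers (0.034), -0.25 for macrophage, lymphoid and blood markers (0.0269) and -0.24 for peritubular and vascular markers (0.0432). These 4 lists had adjusted p = 0.547 with an estimated correlation and 0 members past the threshold, also when adjusted over the list alone. Their calls were lost without MVH precipitate 1 (adjusted p = 0.0586, 0.108, 0.0715 and 0.326) and without total RNA 2 (0.0621, 0.127, 0.0687 and 0.155), that of spermatogonial markers without the dimmest 25% of probes (0.079), and that of peritubular markers without IgG precipitate 1 (0.062) and with no centring (0.0649). Histone genes had a median of -0.42 without total RNA 1, -0.40 without MVH precipitate 2 and -0.09 without MVH precipitate 1, and spermatogonial markers of -0.25 without total RNA 1, -0.26 without MVH precipitate 2 and -0.06 with quantile normalization or without the dimmest 25% of probes. Peritubular markers had one of -0.14 without MVH precipitate 1. Leydig cell markers had a median of -0.26 (camera adjusted p = 0.0473, adjusted p = 0.582 with an estimated correlation), with Cyp17a1 at -1.43, and 2 of 15 were lower when adjusted over the list alone. Without the dimmest 25% of probes their median was 0.06 and the call was lost, as it was with no centring (adjusted p = 0.053), with the median over probes listed on all 6 arrays, chosen after the data were seen (0.0567), and without any 1 array other than total RNA 1 (0.0522 to 0.292, with a median of -0.145 without MVH precipitate 2). The other lists did not pass: piRNA pathway and germ granule proteins (median 0.09), translation initiation factors (0.05), mRNA decay factors (-0.08), proteasome subunits (-0.07), Sertoli cell markers (-0.15), housekeeping genes (-0.22) and division regulators (-0.01). None of these 7 had a member past the threshold, and 1 gene, of the mRNA decay list, passed when adjusted over the list alone. Proteasome subunits passed without total RNA 1 (median -0.21, adjusted p = 0.0335) and without MVH precipitate 2 (-0.12, 0.0493).

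Taking both controls together, 0 probes were higher in the MVH precipitate than in both the IgG precipitate and total RNA by limma's adjusted p. This count was 58 without the dimmest 25% of probes, 43 with an offset, 76 with a variance trend, 12 with probes listed on all 6 arrays, 7 with no centring and 2 with the 75th percentile. Without MVH precipitate 1 it was 6. At an unadjusted p under 0.05, 566 probes were. The lists held 2708 probes higher than with IgG and 975 higher than in total RNA, and independent lists of these sizes would share 124.3. In 50 simulations with unchanged groups the mean was 123.6 and the highest count 148, but the simulated lists were not matched in size to the observed ones. Neither value shows what lists of the observed sizes would share through the MVH arrays common to both comparisons. How much of the overlap comes from these arrays was not tested. By size, 51 probes were at least 2-fold higher in both MVH arrays than in all 4 control arrays, 42 of them with a gene symbol. The largest gaps among named genes, singled out after their values were seen, were in Adam5, Srp54a, the mitochondrial protease gene Yme1l1 and the phosphatase gene Ptpn4. Their differences from total RNA were 2.89, 2.43, 2.68 and 2.15. For scale, 141 probes were at least 2-fold higher in both MVH arrays than in both total RNA arrays, and 391 were so in both IgG arrays.

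The third comparison set the IgG precipitate against total RNA, again by relative level and not by amount. Gsn was 14.3-fold higher in the IgG precipitate than in total RNA (log2 3.84 ± 0.32, SE, n = 2 per group, limma adjusted p = 0.0223), and Trim25 was 8.75-fold higher (log2 3.13 ± 0.29, adjusted p = 0.0251). These were the 2 probes called of 21413, with 0 lower (2002 higher and 1898 lower at an unadjusted p under 0.05). The counts were 112 and 29 with quantile normalization, 150 and 61 with the 75th percentile, 773 and 410 without the dimmest 25% of probes, 660 and 411 with an offset, 798 and 455 with a variance trend, 344 and 125 with probes listed on all 6 arrays, and 0 and 0 without either total RNA array. Many more lay just outside: at an adjusted p under 0.10, a threshold added after the data were seen, 564 were higher and 278 lower. Tex15 differed by 2.47 (adjusted p = 0.0542), Cyp11a1 by 2.32 (0.0631), Acta2 by 2.31 (0.059) and Eif4b by -1.34 (0.0723).

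Leydig cell markers were higher in the IgG precipitate than in total RNA as a group, with a median of 0.77 (camera adjusted p = 0.000241, adjusted p = 0.846 with an estimated correlation), and 5 of 15 were higher when adjusted over the list alone. Without IgG precipitate 1 this median was 0.485, and with no centring it was 0.51. Factors of mRNA decay had a median of 0.29 (camera adjusted p = 0.0055) and division regulators of 0.15 (camera adjusted p = 0.0315), with 4 higher and 1 lower of 53 and 12 higher and 2 lower of 48 when adjusted over the list alone. Both had adjusted p = 0.846 with an estimated correlation. With no centring these medians became 0.03 and -0.11, while the median of all probes went from -0.11 to -0.37. Without IgG precipitate 1 they were 0.11 and -0.04, and the call of division regulators was lost (adjusted p = 0.338), as it was without total RNA 1 (0.11, median 0.08) and with quantile normalization (0.0571), and their median was 0.10 with the 75th percentile. Without IgG precipitate 2 they were 0.50 and 0.31. Round spermatid genes had a median of -0.37 (camera adjusted p = 0.0315) and elongating spermatid genes of -0.37 (camera adjusted p = 0.00263), with 2 higher and 6 lower and 2 higher and 5 lower when adjusted over the list alone. Both again had adjusted p = 0.846 with an estimated correlation. The call of round spermatid genes was lost without IgG precipitate 1 (adjusted p = 0.337) or total RNA 2 (0.126) and with quantile normalization (0.114), and the median of elongating spermatid genes was -0.59 without total RNA 1. With no centring these medians were -0.63 and -0.64. Akap3 differed by -1.67, and Hk1 had scaled intensities of 141 and 176 with IgG against 815 and 489 in total RNA, both short of the threshold.

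The remaining lists did not pass in this comparison. Their medians were 0.18 for piRNA pathway and germ granule proteins, -0.11 for translation initiation factors, -0.16 for ribosomal proteins, -0.01 for the respiratory chain, 0.14 for proteasome subunits, -0.07 for spermatogonial markers and 0.11 for meiotic prophase genes. They were 0.10 for Sertoli cell markers, -0.15 for peritubular and vascular markers, -0.33 for macrophage, lymphoid and blood markers, -0.09 for housekeeping genes and 0.08 for histone genes. Adjusted over the list alone, meiotic prophase genes had 6 higher and 1 lower and piRNA pathway genes 6 higher and 4 lower. Spermatogonial markers had 2 higher, peritubular and vascular markers 3 higher and 1 lower, and proteasome subunits and housekeeping genes 1 lower each. The other 6 lists had 0. Without IgG precipitate 2, piRNA pathway genes (median 0.33, adjusted p = 0.0404) and proteasome subunits (0.36, 0.00651) passed. Without total RNA 2, these lists (0.23, 0.048, and 0.26, 0.0349), meiotic prophase genes (0.15, 0.0349) and respiratory chain genes (0.16, 0.0379) passed, and ribosomal proteins did without total RNA 1 (-0.35, 0.00305) and with an offset (-0.20, 0.0203). Medians of lists that did not pass can differ in sign from their means and from camera, which compares a list with the other genes. This was so for 3 lists between the precipitates, 2 for the MVH precipitate over total RNA and 4 for the IgG precipitate over total RNA.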

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

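The threshold of 0.10 and the median over probes listed on all 6 arrays were chosen after the data had been seen. The groups of every called probe did not overlap, so leaving out an array could not turn a sign. A stable sign was thus largely fixed in advance and is no evidence of robustness. None of the 72 named gene results past the threshold changed sign in 1149 values under the alternatives. Many lost their call, 71 of them when only the groups compared were fitted 71 when MVH precipitate 2 was left out and 72 when either total RNA array was left out. In what follows, counts of probes are given as higher and lower. Between the precipitates the 824 and 895 probes became 1063 and 988 with quantile normalization, 1134 and 924 with the 75th percentile, 748 and 762 with 1 probe per gene, 1126 and 1195 with only probes listed on all 6 arrays, 702 and 121 as deposited, 1492 and 1624 without the dimmest 25% of probes, 1451 and 1502 with an offset, 1507 and 1636 with a variance trend, 1580 and 1687 at a threshold of 0.10, and 0 and 0 when only the groups compared were fitted. For the MVH precipitate over total RNA, 1 and 2 became 14 and 5 as deposited, 5 higher with the 75th percentile, 100 and 23 without the dimmest 25%, 72 and 20 with an offset, 0 and 0 with 1 probe per gene, 132 and 48 with a variance trend, 2 and 4 with only the groups compared, and 23 and 7 with probes listed on all 6 arrays. For the IgG precipitate over total RNA, 2 and 0 became 5 higher as deposited, 112 and 29 with quantile normalization, 150 and 61 with the 75th percentile, 773 and 410 without the dimmest 25%, 660 and 411 with an offset, 80 and 19 with 1 probe per gene, 798 and 455 with a variance trend, 1 higher with only the groups compared, 344 and 125 with probes listed on all 6 arrays, 170 and 49 with the median over those probes, and 564 and 278 at 0.10. Probes higher than in both controls went from 0 to 7 as deposited, 2 with the 75th percentile, 58 without the dimmest 25%, 43 with an offset, 76 with a variance trend, 12 with probes listed on all 6 arrays and 1 at 0.10. The count by size went from 548 to 855 as deposited. The gene lists past the threshold went from 23 of 51 to 0 with an estimated correlation. That setting also tests on the 3 residual degrees of freedom, so a loss of calls was likely whatever the correlation. For macrophage, lymphoid and blood markers in the MVH precipitate over total RNA the estimate was -0.0105, below the preset 0.01. Their unadjusted camera p still went from 0.00949 to 0.0669. Whether correlation alone would remove the calls was not tested. The cause of the other changes was not tested, except that fitting only the groups compared leaves fewer arrays for the spread and the threshold of 0.10 is looser by construction. Leaving out 1 array in turn, with a lone array assumed to vary like the other groups, gave 0 to 593 higher and 0 to 819 lower between the precipitates, 0 to 9 and 0 to 4 for the MVH precipitate over total RNA, 0 to 46 and 0 to 12 for the IgG precipitate over total RNA, 0 to 6 higher than both controls, 548 to 1371 by size and 15 to 25 lists. Between the precipitates the counts were 0 and 0 without MVH precipitate 2, total RNA 1 or total RNA 2, 94 and 16 without MVH precipitate 1, 593 and 424 without IgG precipitate 1, and 508 and 819 without IgG precipitate 2. The count by size was 1371 without MVH precipitate 1, 1357 without IgG precipitate 1 and 1110 without IgG precipitate 2, since fewer arrays had to pass. Without MVH precipitate 1, 15 lists passed. Between the precipitates, the round spermatid, elongating spermatid, Leydig, ribosomal and respiratory lists passed under all 14 settings with the preset correlation, with highest adjusted p-values of 0.00107, 0.00296, 0.00105, 0.00105 and 0.00105. The number of arrays and, for dim probes, the low signal limit these results.

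With the replicate number as a block, 1100 probes were higher and 1163 lower between the precipitates, 3 and 1 for the MVH precipitate over total RNA, 123 and 27 for the IgG precipitate over total RNA, and 2 higher than both controls. By size, 810 probes were 2-fold higher within both pairs of arrays, and 20 lists passed. Those lost were of the MVH precipitate over total RNA, namely elongating spermatid genes (adjusted p = 0.0566) and Leydig and peritubular markers (0.0591 each), whose adjusted p-values ran over all settings with the preset correlation from 0.00205 to 0.677, 0.0168 to 0.292 and 0.0163 to 0.326. The differences between replicates correlated across probes at 0.157 for the MVH and IgG precipitates, 0.156 for the MVH precipitate and total RNA and 0.101 for the IgG precipitate and total RNA. Pairing is not established by this, as the labels do not say that a number marks a shared lysate or day and there are only 2 pairs.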

Other observations

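The 6 gene lists in the next paragraphs, the test of genomic span and the tests of explanations for the Leydig cell difference were chosen after the results had been seen, and so were the genes named here. The lists were drawn up from genes whose values had been seen, so their tests are descriptions and no independent evidence. Several genes of mRNA-binding proteins were higher in the MVH than in the IgG precipitate. Of 32 Y-box and other germ cell mRNA-binding protein genes, 7 were higher and 0 lower, although the list as a whole did not pass (camera adjusted p = 0.12). Besides Ybx1 they were Strap (2.38), Igf2bp3 (2.23), Igf2bp1 (1.66), Ybx3, Cpeb2 (1.37) and Samd4 (1.28). Of 31 DEAD-box helicase genes, 4 were higher, namely Ddx25 (2.51), Ddx49 (2.34), Ddx59 (1.66) and Ddx20 (1.58), and 3 lower, namely Eif4a2, Eif4a1 and Ddx47 (-1.31), with no shift of the list (camera adjusted p = 0.984). Of 30 genes listed under glycolysis and lactate handling, not all of them enzymes of glycolysis, 6 were higher and 3 lower (camera adjusted p = 0.293). The higher ones included Hk1, Gpd2 (2.68), Ldha (2.64) and Tpi1 (1.49), and the lower ones were Pgam1 (-2.11), Ldhb (-1.56) and Pfkl (-1.53). Of 29 ADAM protease genes, Adam5 and Adam21 (1.79) were higher (camera adjusted p = 0.074). Of 25 genes listed under cholesterol and steroid synthesis, 6 of them also in the Leydig cell list, 2 were higher, Idi1 (1.41) and Fdft1 (1.28), and 7 lower (camera adjusted p = 0.074). The lower ones were Cyp17a1, Cyp11a1, Hsd3b1 and Hsd3b6, all of the Leydig cell list, and Ephx1 (-2.47), Ebpl and Sult1e1. Not every member is a synthesis enzyme, as Sult1e1 is an estrogen sulfotransferase gene.

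Against total RNA, the list of centrosome and centriolar satellite proteins lay above 0 in both precipitates. The medians were 0.52 with MVH (camera adjusted p = 1.82e-07, adjusted p = 0.39 with an estimated correlation) and 0.46 with IgG (camera adjusted p = 0.000478, adjusted p = 0.833 with an estimated correlation). Both comparisons share the total RNA arrays, which alone makes them alike, and no member passed alone. Pcm1 differed by 2.93 with MVH and 2.57 with IgG, Cep290 by 2.46 and 1.90, and Kif15 by 2.37 and 2.04. Between the precipitates 3 of 32 were higher and 1 lower (camera adjusted p = 0.61). In the MVH precipitate over total RNA, ADAM protease genes had a median of 0.30 and cholesterol and steroid genes of -0.24 (camera adjusted p = 0.00154 for each, adjusted p = 0.39 with an estimated correlation). The glycolysis, DEAD-box and mRNA-binding lists did not pass there (0.205, 0.227 and 0.104), nor did these 5 lists in the IgG precipitate over total RNA (0.58 for 4 of them and 0.782 for ADAM proteases).

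Limma separated the MVH from the IgG precipitate at 1719 probes but the MVH precipitate from total RNA at 3 and the IgG precipitate at 2, which became 100 higher and 23 lower for MVH and 773 higher and 410 lower for IgG without the dimmest 25% of probes. A single aberrant array is argued against, since the difference between the precipitates correlated across probes at 0.486 or more between pairs with no array in common. Departures of the IgG precipitate from total RNA correlated at 0.371 or more between such pairs. This argues against random noise of amplification in the IgG precipitate only if its 2 arrays were amplified separately, which the labels do not say. Probes in the dimmest 25% made up 6.22% of the calls, which argues against dim probes as the source. Of the 824 probes highest in 1 MVH array over 1 IgG array, the held-out MVH array lay above total RNA by a median of at least 0.412 on the log2 scale relative to all probes. The held-out IgG array lay below total RNA by a median log2 of -0.428 or lower. These probes were chosen on 1 pair of arrays and not by limma. They may hold both enrichment with the antibody and lower recovery with IgG. Of the 824 lowest probes, the held-out IgG array lay above total RNA by a median log2 of 0.73 to 0.907 relative to all probes. The held-out MVH array lay below total RNA, at a median log2 of -0.134 to -0.33 relative to all probes. The lowest probes thus lay more on the side of gain with IgG. How far the chosen probes overlap with the called ones was not counted. A reproducible bias of recovery or amplification in either precipitate stays open for both the higher and the lower calls, because RNA yields are not given in the sources used here.

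A hypothesis written before the centrosome genes were tested was that a step shared by both precipitates, and not by total RNA, shifts many genes alike. Over all 8 pairings with no array in common, where the hypothesis had been written down for 4, the departures of the precipitates from total RNA correlated across probes at -0.164 to 0.034. This argues against such a step as the main influence on the whole profile but does not measure its size. Each precipitate's own departures correlated at only 0.256 and 0.405 (MVH) and 0.371 and 0.451 (IgG), and opposite shifts of the precipitates could cancel a shared one. Spearman correlations with the genomic span of the gene, a rough proxy of transcript size, over 15073 genes were 0.063 for the IgG precipitate and 0.207 for the MVH precipitate. Transcript size cannot be told apart from other causes with this proxy, since introns make up most of a span and the correlations lay on both sides of the bounds set. Probes and genes are not independent replicates.

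The Leydig cell list was higher in the IgG than in the MVH precipitate, with 13 of 15 members in this direction and 6 past the threshold. With an estimated correlation the list did not pass (camera adjusted p = 0.61). More Leydig cells in the tissue behind the IgG precipitate would raise their markers alike if nothing else differed from total RNA. The SD of the 15 members' log2 differences from total RNA was 0.71, 2.35 times their median SE. This lay above the bound set against more Leydig cells, a bound written after the results had been seen. Over all probes the SD was 0.58 with a median SE of 0.31, so genes in general varied nearly as much. The 6 steroid synthesis genes, which are largely restricted to these cells, ranged from 0.08 ± 0.32 (SE, Hsd17b3), no clear rise, to 2.32 ± 0.45 (Cyp11a1). Scarb1 (-0.30), Aldh1a1 (-0.23) and Srd5a1 (-0.12) went the other way. Some other members, such as Aldh1a1, Por and Idh1, are expressed in further cell types. More Leydig cells therefore stay open, since a common rise on top of the general variation would also give such values. Depletion from the MVH precipitate as the only cause is argued against with all 6 arrays, since the median over total RNA was 0.77 with IgG, with 12 of 15 members higher, and -0.26 with MVH, short of the -1.01 that it would need by 1.24 SDs of the members, but by only 0.271 SDs without IgG precipitate 1 and 0.985 without MVH precipitate 1. Depletion as a part of the cause stays open, as 53.3% of the members were lower in the MVH precipitate than in total RNA, and so does nonspecific binding of particular transcripts to IgG beads, a candidate explanation that was not tested.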
